A study of Homo sapiens with 57 samples.

How the data were processed

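RNA sequencing had been done on 57 kidney allograft biopsies. Per the labels, total RNA was prepared with the miRNeasy mini kit and libraries with the TruSeq kit. The biopsies fell into 4 groups by their Banff diagnosis, which grades rejection on histology: 15 with chronic active antibody-mediated rejection (caABMR), 7 with active antibody-mediated rejection (aABMR), 17 with acute T cell-mediated rejection (TCMR) and 18 without rejection (NoRejection). Each biopsy had 1 deposited file with FPKM values, fragments mapped to a transcript scaled by its length and by the mapped total, made by the authors for 59394 gene symbols. The submitters' processing notes name Trim Galore, STAR, HTSeq and Cufflinks and the genome builds GRCh38 and hg38, without versions. The gene annotation and any further normalization are not given in the sources used here. All per-sample columns were mapped to a biopsy, and 0 were left over. No pair among the 1596 pairs of biopsies held identical values, and correlations of log2(FPKM + 1) between biopsies ranged from 0.699 to 0.975.

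Library depth is not given with FPKM, and the counts behind a value cannot be recovered from it. No counting interval or detection limit is therefore given, and the precision of each value rests on the spread between biopsies. The sum of FPKM per biopsy ranged from 280956 to 576847, and 12588 to 16700 symbols reached an FPKM of 1. For 241 symbols the values carry more than 6 significant digits, as a mean over several loci would give, and 75 of these passed the filter below. Of 4147 symbols with a median FPKM over 10, 16 were listed at 0 in at least 1 biopsy. Symbols were matched to GENCODE release 29 for gene identifiers and GRCh38 positions, and 54375 of the 59394 symbols were found there. Symbols on chromosome Y and of the XIST region, 520 in all, were left out of every table and test.

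The sample titles come in 3 forms, taken here as library batches and called index (21 biopsies), letterA (27) and prefixed (9). The index form held 8 caABMR, 4 aABMR, 4 TCMR and 5 NoRejection biopsies. The letterA form held 7 caABMR, 1 aABMR, 6 TCMR and 13 NoRejection biopsies. The prefixed form held 2 aABMR and 7 TCMR biopsies and none of the other groups. The share of each gene's variance taken by title form and by group was computed on log2(FPKM + 1).

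Genes with an FPKM of at least 1 in at least 7 biopsies, the size of the smallest group, were tested, which left 17637. Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with trend and robust, the latter through statmod 1.5.0). The model had a term for group and a term for title form and used all 57 biopsies with 1 shared spread. P-values were adjusted by the method of Benjamini and Hochberg within each of 5 comparisons, and a gene was called at an adjusted p under 0.05; a second count also required a 2-fold change. The comparisons were caABMR against NoRejection, aABMR and TCMR, and aABMR and TCMR against NoRejection. Fold changes are limma estimates adjusted for title form, and their error is the standard error (SE) of the moderated fit.

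Of 25 gene lists with 574 distinct genes, 503 genes passed the filter. The lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined. A list score is the mean log2(FPKM + 1) of a list's tested members in a biopsy. The score difference between groups was taken within title form, weighted by n1 n2 / (n1 + n2), so that prefixed biopsies entered no comparison of scores with a group that has none. Group labels were permuted within title form in a two-sided test, with all permutations in the exact tests that involve aABMR, where 5 of the 7 aABMR biopsies enter, and 100000 resamples in the others, where the smallest possible p is 1e-05. Adjustment was over all 125 list tests. The score of 15 NK cell markers minus that of 23 T cell genes was tested in the same way, between caABMR and TCMR as fixed before and in the other comparisons after the data were seen. Also after the data were seen, log2 sums of FPKM over 6 gene families were tested in this way (30 tests), as was the spread of the 25 scores in TCMR against caABMR. Dixon's ratio was used to look for a biopsy apart from the rest in the group of 7. Bootstrap intervals (95%) came from 10000 draws within group and title form. As a competitive test, limma's camera was run with its preset correlation of 0.01 and with an estimated one. In each list, calls are given as adjusted over all genes and as adjusted over the list alone. The list called NK cytotoxicity pathway follows the pathway that the series title names for these same samples, so its direction in caABMR is not independent evidence. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

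The genes named were chosen by a rule. It takes per comparison the 8 called genes with the largest positive and the 8 with the largest negative log2 change that kept their direction in every title form with at least 2 biopsies of both groups and had a mean FPKM of at least 1 in either group. It adds the 4 members with the smallest p in each list described, and 16 genes named always: PRF1, GZMB, GNLY, NKG7, KLRD1, FCGR3A, IFNG, CD8A, CD3E, CXCL9, CXCL10, MS4A1, PECAM1, COL1A1, HAVCR1 and SLC34A1. IFNG did not pass the filter and has no value.

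Alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, upper-quartile scaling, quantile normalization, no term for title form, the 2 compared groups alone, array quality weights, the index or letterA form alone, and the fit without each aABMR biopsy in turn. After the data were seen, 4 more were added: the 37 mitochondrial transcripts or the 100 most abundant genes left out with the rest rescaled, the prefixed form left out, and 4 biopsies left out whose median correlation with the others was lowest. List scores were also taken with z-scores, with medians, over all biopsies without regard to title form, with members of no other list, with upper-quartile scaling and, added after the data were seen, without mitochondrial transcripts, without each biopsy in turn and without the 4 of lowest correlation. The letterA form alone could not be fitted for aABMR, with 1 biopsy there. Tests on simulated independent normal values used the data's means, title form effects and 1 residual spread per gene for all groups. Of 100 genes changed 2-fold, 97, 83, 90, 83 and 94 were recovered in the 5 comparisons as listed. Of 100 changed 1.5-fold, 75, 43, 61, 44 and 76 were. False calls were 7 to 13. Real genes correlate and vary in spread by group, so real recovery is unknown. Between 4.6% and 5.55% of 2000 unchanged simulated list scores had a permutation p under 0.05.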

Results

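Transcript levels were measured as FPKM in 57 kidney allograft biopsies: 15 caABMR, 7 aABMR, 17 TCMR and 18 NoRejection. The series asks how the transcripts of natural killer (NK) cell cytotoxicity in caABMR differ from those of active antibody-mediated rejection, T cell-mediated rejection and grafts without rejection. The sum of FPKM averaged 398788 ± 49121 (SD, n = 15) in caABMR, 390238 ± 18419 (n = 7) in aABMR, 383993 ± 48455 (n = 17) in TCMR and 431677 ± 58662 (n = 18) in NoRejection; read depth is unknown. Transcripts of the mitochondrial genome took 35.0% ± 6.8 (SD, n = 15) of FPKM in caABMR, 33.9% ± 7.0 (n = 7) in aABMR, 35.5% ± 7.8 (n = 17) in TCMR and 44.9% ± 6.7 (n = 18) in NoRejection. The form of the sample title took a median of 11.8% of a gene's variance and the group 15.1%. Title form took 58.8% of the second principal component and group 7.0% of it, and on the first the shares were 35.2% and 31.7%. The 4 biopsies least correlated with the rest were caABMR replicate 9, NoRejection replicate 12 and TCMR replicates 1 and 15. In caABMR 9, NoRejection 12 and TCMR 15 the proximal tubule score was 1.57, 2.02 and 1.88, against group means of 5.99, 6.30 and 5.26. Their collecting duct scores were 4.80, 4.84 and 4.70, against 3.75, 4.03 and 3.78. They had the highest values on the second component (75.7, 74.9 and 73.9), so title form is not all that it carries. TCMR replicates 2, 5 and 13 came next on it, at 59.1, 59.0 and 53.1. Their proximal tubule scores were 3.6, 3.0 and 3.1 and their collecting duct scores 4.4, 4.4 and 4.9. Biopsies of this kind were thus mostly TCMR, which the main comparisons do not adjust for. The cause was not tested. Each biopsy was left out of the list scores in turn after the data were seen.

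**Figure D1:**
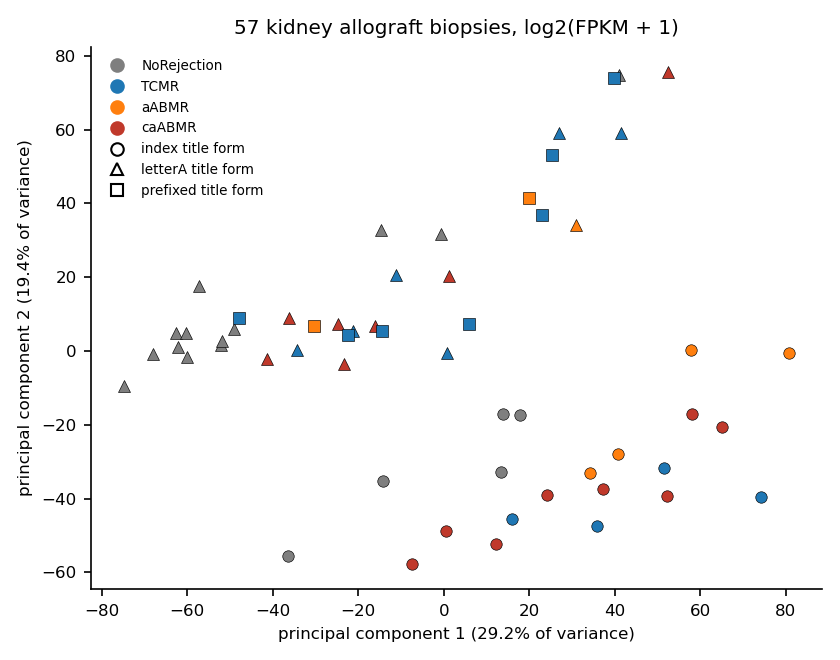
Each point is 1 of the 57 biopsies on the first principal component (x axis, 29.2% of variance) and the second (y axis, 19.4%) of log2(FPKM + 1), with color for group and shape for title form. The index biopsies lie toward lower values of the second component than the other forms, which hold the values furthest above 0.

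The comparison of caABMR with NoRejection asks what chronic active antibody-mediated rejection adds to a graft without rejection. Chemokine, cytotoxic effector and interferon gamma response genes were higher (camera adjusted p between 0.258 and 0.269 with an estimated correlation). CXCL9, a ligand of the T and NK cell receptor CXCR3 (chromosome 4, 76001275 to 76007488, GRCh38), averaged 37.1 ± 18.1 FPKM (SD, n = 15) against 3.15 ± 3.44 (n = 18), a log2 change of 3.10 ± 0.65 (SE, adjusted p = 0.000407). GNLY, which encodes the lytic granule protein granulysin (chromosome 2, 85685175 to 85698854), averaged 12.4 ± 6.72 against 1.48 ± 1.07 (log2 change 2.33 ± 0.38, adjusted p = 2.47e-05). PVALB, a calcium-binding protein of the distal convoluted tubule (chromosome 22, 36800684 to 36819479), averaged 5.52 ± 4.33 against 23.1 ± 10.7 (log2 change -2.04 ± 0.32, adjusted p = 1.94e-05) and lay below the NoRejection median in 15 of 15 caABMR biopsies.

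In the NK cytotoxicity pathway, 57 of 86 tested members rose, 0 fell and 29 did not pass (61 rose when adjusted over the list alone). Its score was higher by 0.65 (95% interval 0.53 to 0.77, adjusted permutation p = 0.000114, above the NoRejection median in 15 of 15 biopsies). This pathway is the one the series names for these samples, so its count is not independent evidence; with an estimated correlation its camera adjusted p = 0.269. Members with the smallest p were HLA-E, an inhibitory NK cell ligand (log2 change 1.08), the adhesion molecule ICAM1 (1.44), the death receptor FAS (0.95) and the IgG receptor FCGR3A (2.35 ± 0.37, chromosome 1, 161541759 to 161550737), whose sequence is close to that of FCGR3B. NK cell markers were higher by 1.21 (adjusted permutation p = 0.000114), with 14 of 15 members risen, among them the fractalkine receptor CX3CR1 (1.15), the lectin receptor KLRB1 (1.15) and KLRD1 (0.95 ± 0.22), the CD94 subunit of NK receptors. Cytotoxic effectors were higher by 1.37 (11 of 12 rose, 12 over the list alone), with PRF1 for perforin at 1.46 ± 0.27, NKG7 at 1.91 ± 0.35 and GZMB for granzyme B at 1.33 ± 0.37. T cell genes were higher by 1.00 (20 of 23 rose, 21 over the list alone), with CD3E at 1.52 and CD8A at 1.29. Each of these 3 scores had an adjusted permutation p of 0.000114, from the smallest p that 100000 resamples can give. For them, camera with an estimated correlation gave adjusted p between 0.189 and 0.378.

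The interferon gamma response had 30 of 31 tested members risen (30 over the list alone) and a score higher by 1.56 (95% interval 1.28 to 1.80, adjusted permutation p = 0.000114; camera adjusted p = 0.258 with an estimated correlation). CXCL10 rose by 2.60 ± 0.52, the guanylate-binding protein GBP2 by 1.60 and B2M, the light chain of HLA class I, by 1.31. Among other leukocyte lists, macrophages and monocytes were higher by 1.16 (17 of 21 rose, 20 over the list alone), with the transcription factor SPI1 at 1.43, and plasma cells by 1.63 (12 of 14 rose). Mast cells were higher by 0.93 (5 of 6 rose) with the protease genes CPA3 (0.98) and TPSAB1 (1.46, nearly identical in sequence to TPSB2), neutrophils by 0.73 (2 of 4 rose, 3 over the list alone) and B cells by 0.57 (3 of 7 rose, 4 over the list alone), with MS4A1 for CD20 at 0.85 ± 0.28. Chemokines were higher by 1.19 (15 of 21), complement by 0.95 (15 of 20), with C1QB at 1.88, and the type I interferon response by 0.68 (17 of 20). Adjusted permutation p for these 8 scores lay between 0.000114 and 0.00225. Camera's adjusted p for them with an estimated correlation lay between 0.262 and 0.628.

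Endothelial genes were higher by 0.65 (95% interval 0.43 to 0.90, adjusted permutation p = 0.000197; camera adjusted p = 0.269 with an estimated correlation). Of 30 members 19 rose (21 over the list alone), among them the adhesion molecule PECAM1 (1.17 ± 0.20), the phospholipase PLA1A (1.40) and the endothelial receptor ROBO4 (0.91). Extracellular matrix and fibroblast genes were higher by 0.57 (12 of 29 rose), tubular injury by 0.63 (9 of 28), and immediate early and heat shock genes by 0.50 (12 of 16), with adjusted permutation p of 0.00303, 0.00186 and 0.000139. For them, camera with an estimated correlation gave adjusted p between 0.406 and 0.628. COL1A1, a chain of type I collagen, changed by 0.28 ± 0.41 (adjusted p = 0.628) and HAVCR1, the tubular injury marker KIM-1, by 0.61 ± 0.26 (adjusted p = 0.0722). Proliferation was higher by 0.17 (adjusted permutation p = 0.00259; camera adjusted p = 0.993 with an estimated correlation) with 1 of 17 members risen and 0 over the list alone; its median member lay 0.04 above the median of all genes, and upper-quartile scaling ended the call. Oxidative phosphorylation was lower, at -0.34 (22 of 27 fell, 26 over the list alone, adjusted permutation p = 0.00455), with UQCRC1 of complex III at -0.44 and NDUFV1 of complex I at -0.37. That call ended when permutation ignored title form, where the difference was -0.22, and with an estimated correlation the camera adjusted p = 0.182. The mitochondrial share of FPKM was lower in the same biopsies, as given above. Loop of Henle and distal tubule genes were lower, at -0.59 (3 of 15 fell, 2 over the list alone, adjusted permutation p = 0.00505; camera adjusted p = 0.189 with an estimated correlation), including EGF (-1.09). The test was not passed by fatty acid oxidation and peroxisome (-0.22, adjusted p = 0.057, 3 of 22 fell), collecting duct (-0.18, adjusted p = 0.251), podocytes (0.15, adjusted p = 0.509, 3 of 14 rose; 0.056 without NoRejection replicate 13), proximal tubule (-0.37, adjusted p = 0.551; 0.040 without caABMR replicate 9 and -0.58 without NoRejection replicate 12; the phosphate transporter SLC34A1 at -0.23 ± 0.78) or red blood cells (-0.37, adjusted p = 0.315). Of the 33 biopsies left out in turn none ended a list call here, and 8 gave one to fatty acid oxidation. Collecting duct was at -0.10 without caABMR replicate 12 and red blood cells at -0.25 without caABMR replicate 11.

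The other genes with the largest changes were immunoglobulin constant regions of heavy and lambda chains, whose near-identical sequences leave open which gene a read came from: IGHG1 (log2 change 3.29), IGLC1 (2.87), IGHG3 (2.80), IGLC3 (2.74) and IGHG2 (2.57), beside IGKC (2.87), the single constant region of kappa chains. Among the falls were the kidney kallikrein KLK1 (-1.71), the antimicrobial peptide gene DEFB1 (-1.47, from 730.5 ± 345 to 273.7 ± 127 FPKM), glucose-6-phosphatase G6PC (-1.40), the lectin ITLN1 (-1.22), the metallothionein MT3 (-1.07) and BCYRN1 (-1.19), an RNA with copies at many loci. By limma, 5168 of 17637 genes were called, 4686 higher and 482 lower. At least 2-fold changes were found in 400, 388 higher and 12 lower, and in 1014 (979 and 35) at a pseudocount of 0.1. The median of all genes was higher by 0.14. Relative to it, the median member of the interferon gamma list lay at 1.28, of the NK cell markers at 0.99 and of the NK cytotoxicity pathway at 0.28. Higher calls were 90.7% of all calls, 59.9% with upper-quartile scaling, 50.4% with quantile normalization and 78.8% without mitochondrial transcripts. Against other genes, camera called 21 of 25 lists with its preset correlation and 0 with an estimated correlation (adjusted p = 0.182 at the lowest). Its direction was down for podocytes and proliferation, against the sign of their scores. Within title forms the calls fell to 1570 (index) and 1916 (letterA).

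**Figure D2:**
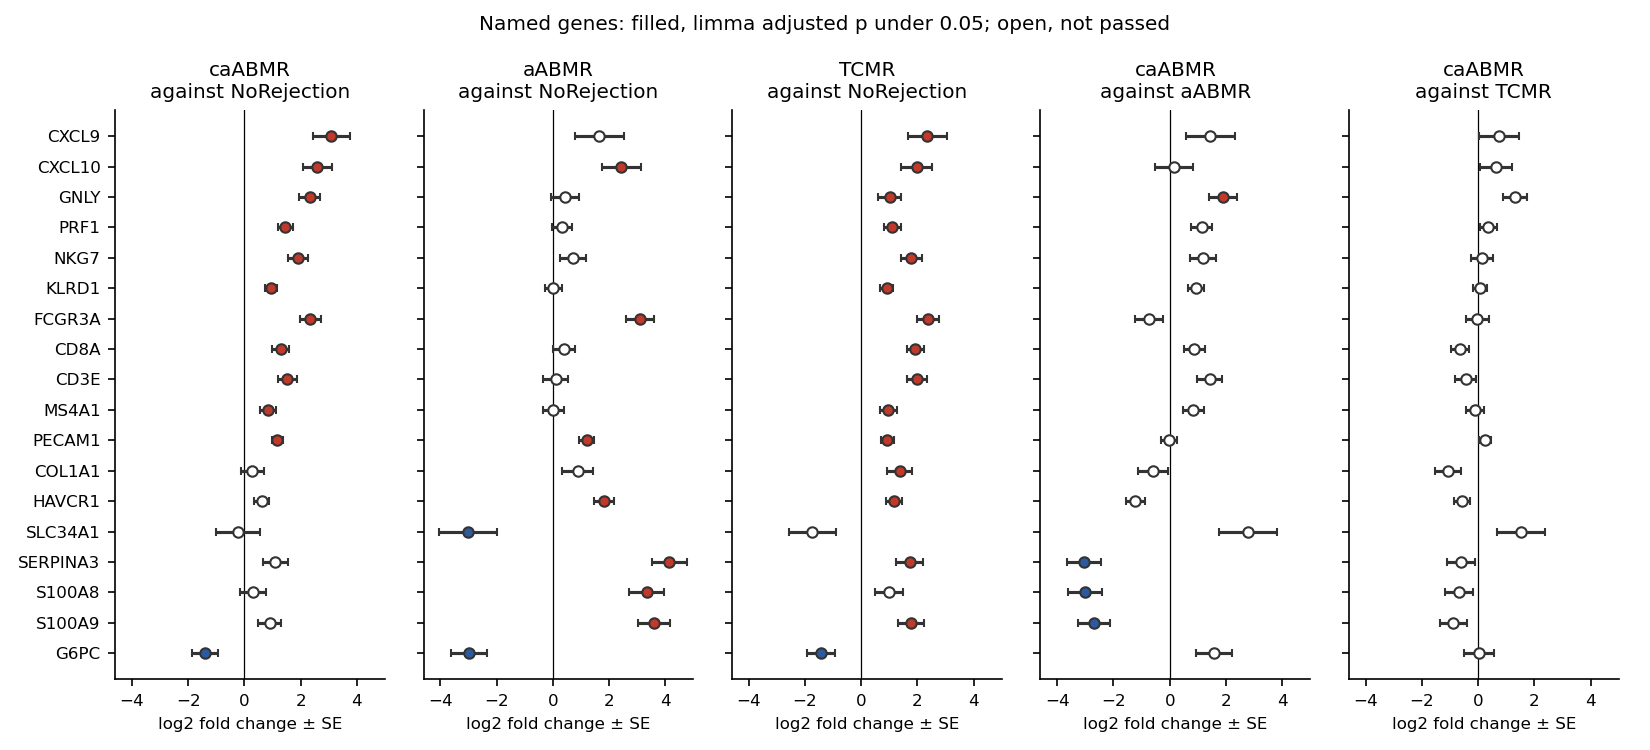
Log2 fold change (x axis) with its SE for 18 named genes (y axis) in each of the 5 comparisons; filled points have a limma adjusted p under 0.05. CXCL9 is at 3.10 in caABMR against NoRejection, and SERPINA3 is at -3.05 in caABMR against aABMR.

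The comparison of caABMR with aABMR asks what separates the chronic active from the active form of antibody-mediated rejection. Its list scores rest on 5 of the 7 aABMR biopsies, as the other 2 are of the prefixed form, which holds no caABMR. NK, T and mast cell transcripts were higher in caABMR, and genes of tubular injury and of neutrophils were lower. Against other genes, camera with an estimated correlation called 0 of these 5 lists (adjusted p between 0.0815 and 0.269). The score calls of T cells, tubular injury and neutrophils ended when 1 aABMR biopsy was left out. KLRB1, the receptor CD161 of NK and T cells (chromosome 12, 9594551 to 9607886), averaged 2.31 ± 1.22 FPKM (SD, n = 15) against 0.436 ± 0.422 (n = 7), a log2 change of 1.19 ± 0.23 (SE, adjusted p = 0.00863). SERPINA3, an acute-phase protease inhibitor (chromosome 14, 94612377 to 94624055), averaged 6.07 ± 5.73 against 96.3 ± 92.9 (log2 change -3.05 ± 0.61, adjusted p = 0.00897). S100A8, a calcium-binding protein of neutrophils and monocytes (chromosome 1, 153390032 to 153391188), averaged 3.42 ± 3.60 against 113.7 ± 176 (log2 change -3.02 ± 0.61, adjusted p = 0.00897), and all 15 caABMR biopsies lay below the aABMR median for both genes. Without aABMR replicate 1 the last 2 calls ended (adjusted p = 0.0611 and 0.0691), and of 30 named genes called here 2 stayed called, KLRB1 and CHRDL1. Only KLRB1 stayed called without each of the 7 in turn.

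NK cell markers were higher in caABMR by 0.71 (exact permutation, adjusted p = 0.0118), with 5 of 15 members risen (10 over the list alone): KLRB1, GNLY (1.89 ± 0.51), the delta chain TRDC (1.20), the killer lectin receptor KLRF1 (0.60) and FGFBP2 (0.75), a secreted protein of cytotoxic cells. With an estimated correlation the camera adjusted p = 0.182 for this list. Cytotoxic effectors were higher by 0.74 (exact permutation, adjusted p = 0.0306), with 1 of 12 risen and 1, TNFSF10 for the death ligand TRAIL, fallen (-0.97); over the list alone 8 rose and 2 fell. T cell genes were higher by 0.70 (exact permutation, adjusted p = 0.023) with 0 of 23 called over all genes and 11 over the list alone. With an estimated correlation camera gave adjusted p = 0.317 for cytotoxic effectors and 0.269 for T cells. The cytotoxic effector call ended without aABMR replicate 1, 4 or 5 (0.68, 0.67 and 0.64) and the T cell call without replicate 1 or 5 (0.62 and 0.63). Within the index form these 3 scores differed by 0.88, 1.04 and 0.88; the letterA form, with 1 aABMR biopsy, gave 0.20, -0.15 and 0.18. Mast cells were higher by 0.92 (exact permutation, adjusted p = 0.00329), with 4 of 6 risen (5 over the list alone), including CPA3 (1.11) and TPSAB1 (1.38); with an estimated correlation the camera adjusted p = 0.0815. The mast cell differences were 0.80 and 1.28 within the index and letterA forms. The NK cytotoxicity pathway differed by 0.04 (exact permutation, adjusted p = 0.824), with 0 of 86 risen and 2 fallen (7 and 10 over the list alone). Its median member was at -0.04, opposite in sign to the score.

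Tubular injury was lower in caABMR, at -0.96 (exact permutation, adjusted p = 0.0144; camera adjusted p = 0.235 with an estimated correlation), with 8 of 28 fallen (13 over the list alone), among them SERPINA3, the secreted phosphoprotein SPP1 (-1.93 ± 0.41) and the chemokine CXCL8 (-1.58). The difference was -0.74 in the index form, where the exact permutation p = 0.0667 over 12 biopsies, and -1.61 in the letterA form. Neutrophil genes were lower, at -0.89 (adjusted exact p = 0.0181, 3 of 4 fell), with the growth factor receptor CSF3R at -1.28 and the formyl peptide receptor FPR1 at -1.48. Immediate early and heat shock genes were lower, at -0.56 (adjusted exact p = 0.0174, 3 of 16 fell, 8 over the list alone), with JUNB at -1.24 and FOS at -1.28. Proliferation was lower, at -0.55 (adjusted exact p = 0.0306, 1 of 17 fell, 10 over the list alone), by -0.23 in the index form and -1.53 in the letterA form. Camera's adjusted p with an estimated correlation was 0.262 for neutrophils, 0.269 for immediate early genes and 0.269 for proliferation. Without aABMR replicate 3 these 3 calls and that of tubular injury ended, with proliferation at -0.23. Without replicate 1 the calls of neutrophils (-0.56) and immediate early genes (-0.40) ended, and without replicate 4 that of proliferation (-0.46). Fatty acid oxidation and peroxisome scored higher by 0.45 (adjusted exact p = 0.00231; camera adjusted p = 0.269 with an estimated correlation) with 0 of 22 members called on either basis. The exact test was not passed by macrophages and monocytes (-0.59, adjusted p = 0.0702, 3 of 21 fell), proximal tubule (1.33, adjusted p = 0.0717), extracellular matrix and fibroblasts (-0.61, adjusted p = 0.0525; the protease inhibitor TIMP1 at -1.80 was 1 of 2 that fell) or B cells (0.50, adjusted p = 0.168). The adjusted exact p was also above 0.05 for collecting duct (0.33, 2 of 16 rose), interferon gamma response (0.31), type I interferon response (0.0021), chemokines (0.14, 2 of 21 fell), complement (-0.03, 1 of 20 fell), endothelium (0.01, 1 of 30 rose), oxidative phosphorylation (0.16), plasma cells (0.57), podocytes (0.21), loop of Henle and distal tubule (0.21) and red blood cells (0.08). Single aABMR biopsies moved these values. Without replicate 3 macrophages and monocytes were at -0.18, extracellular matrix at -0.31, collecting duct at 0.085, podocytes at 0.084, chemokines at 0.33 and interferon gamma response at 0.66, the last with a call. Without replicate 2 macrophages and monocytes were at -0.84 with a call, B cells were called without 5 (0.72) and extracellular matrix without aABMR 1, 2 or 5 or caABMR 6, 8 or 10. Without caABMR replicate 9 proximal tubule was called (adjusted exact p = 0.00681), and without caABMR replicate 2 oxidative phosphorylation was at 0.10. Over the 20 omissions plasma cells ranged from 0.28 to 0.94 and loop of Henle from 0.0040 to 0.47, and the sign turned in at least 1 of them for complement, endothelium, red blood cells, type I interferon and the NK cytotoxicity pathway. Median members were of the opposite sign for loop of Henle, red blood cells and type I interferon, as was the camera direction for chemokines and type I interferon.

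The other rises at the top were APOC3 for an apolipoprotein (2.12), ERICH4 (1.78), TRAC, the constant region of the T cell receptor alpha chain (1.67), CHRDL1, an antagonist of bone morphogenetic proteins (1.56), VWF for von Willebrand factor (1.54 ± 0.39), AL121992.3 (1.51) and ATP6V1B1, a proton pump subunit of intercalated cells (1.47). The other falls were AP000944.3 (-3.69 ± 0.86), S100A9 (-2.69), LCN2 for the injury marker NGAL (-2.47), RASD1 (-2.03), the phosphate transporter SLC34A2 (-2.02) and the integrin chain ITGB6, which went from 40.2 ± 29.3 FPKM in aABMR to 8.92 ± 8.51 in caABMR. The fixed genes that did not pass were PRF1 (1.14, adjusted p = 0.0874), GZMB (0.82), NKG7 (1.19), KLRD1 (0.94), FCGR3A (-0.74, with 0.27 in the index form), CD8A (0.88), CD3E (1.42), CXCL9 (1.45), CXCL10 (0.16), MS4A1 (0.83), PECAM1 (-0.03), COL1A1 (-0.59), HAVCR1 (-1.22, adjusted p = 0.0562) and SLC34A1 (2.80 ± 1.03, adjusted p = 0.145). By limma, 295 genes were called, 118 higher and 177 lower in caABMR, and another split of the same biopsies gave 291. Of the 295, 80 changed at least 2-fold, 29 higher and 51 lower. That balance turned to 72 higher and 53 lower at a pseudocount of 0.1, 286 and 81 with array weights, 240 and 70 without the 4 least correlated biopsies and 105 and 79 without aABMR replicate 7. The number was 134 without replicate 2 and 8, 30, 38 and 28 without replicates 1, 3, 4 and 6. Higher calls were 40.0% of all calls, 53.6% at a pseudocount of 0.1, 33.3% with upper-quartile scaling, 29.6% without the filter and 27.7% with quantile normalization. Camera called 17 of 25 lists with its preset correlation and 0 with an estimated correlation, where the lowest adjusted p = 0.0815 belonged to mast cells. The count rests on few aABMR biopsies: it was 28 without aABMR replicate 1, 69 without replicate 3, 133 without replicate 4, 90 without replicate 6, 578 without replicate 2 and 767 without replicate 7. It was 3 with the 2 compared groups alone and 6 in the index form alone.

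The comparison of caABMR with TCMR asks whether the 2 kinds of rejection differ. No gene was called by limma (0 of 17637), with 1624 genes at an unadjusted p under 0.05, and the differences that passed were between list scores. Endothelial genes scored higher in caABMR by 0.46 (95% interval 0.24 to 0.70, adjusted permutation p = 0.00365) and above the TCMR median in 13 of 15 biopsies, but with an estimated correlation the camera adjusted p = 0.0815. In this list 0 of 30 members were called over all genes and 15 rose over the list alone. The gene nearest to a call was ROBO4 (chromosome 11, 124883691 to 124898500), at 10.1 ± 5.72 FPKM (SD, n = 15) against 5.68 ± 1.95 (n = 17), a log2 change of 0.85 ± 0.16 (SE, adjusted p = 0.0577). NK cell markers minus T cell genes, the balance of the 2 lists in each biopsy, averaged 0.337 ± 0.309 (SD, n = 15) in caABMR and -0.182 ± 0.414 (n = 17) in TCMR. The difference within title form was 0.66 (95% interval 0.41 to 0.92, permutation p = 8e-05), and 13 of 15 caABMR biopsies lay above the TCMR median. Score tests in this comparison use 25 biopsies, without the 7 TCMR biopsies of the prefixed form. Over all 32 biopsies the balance differed by 0.52 (permutation p = 0.00041).

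**Figure D3:**
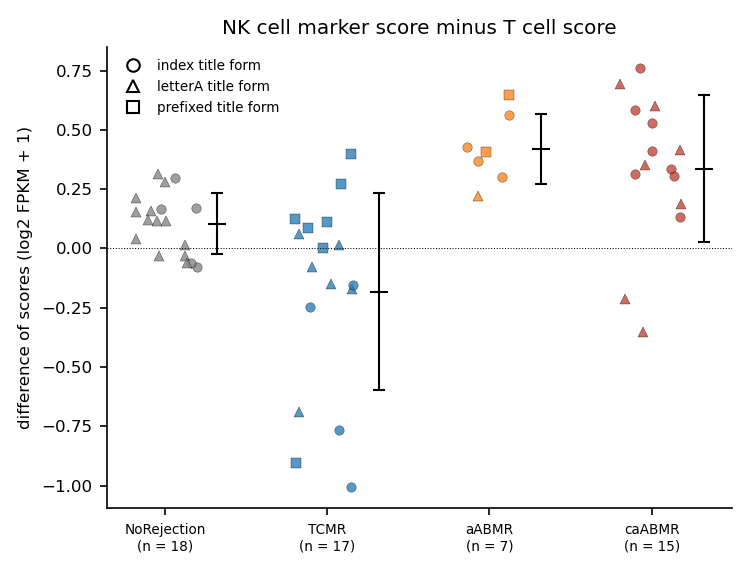
NK cell marker score minus T cell score (y axis, log2 FPKM + 1) of each biopsy by group (x axis), with shape for title form and bars for mean ± SD. The caABMR mean is 0.337 and the TCMR mean is -0.182.

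The members behind the endothelial score were PLA1A (log2 change 1.02 ± 0.24, adjusted p = 0.137), the cell-surface protein ECSCR (0.58) and the transcription factor SOX7 (0.36) besides ROBO4, and none passed over all genes; PECAM1 was at 0.24 ± 0.22. Endothelium differed by 0.57 in the index form and 0.37 in the letterA form. Endothelium minus collecting duct differed by 0.318 (permutation p = 0.148). Podocytes scored higher by 0.50 (adjusted permutation p = 0.0434, 0 of 14 called, 2 over the list alone), with 0.51 and 0.49 within the index and letterA forms, nestin (NES) at 0.73, podocalyxin (PODXL) at 0.80, the phospholipase receptor PLA2R1 at 0.58 and WT1 at 0.57. A pseudocount of 0.1 or medians in place of means ended this call, and with an estimated correlation the camera adjusted p = 0.182. It also ended in 14 of the 25 omissions of 1 biopsy, with 0.39 at the lowest. Proliferation scored lower, at -0.43 (adjusted permutation p = 0.0366, 0 of 17 called, 11 fallen over the list alone), with MKI67 at -0.55 and TOP2A at -0.59, and by -0.67 and -0.23 within the forms. Neutrophils scored lower, at -0.64 (adjusted permutation p = 0.0377, 0 of 4 called, 1 over the list alone), with MMP9 at -0.95, and by -1.14 and -0.23 within the forms. The last 2 calls ended when permutation ignored title form and with medians, and that of neutrophils also at a pseudocount of 0.1. Both ended without TCMR replicate 1 (-0.27 and -0.43, adjusted permutation p = 0.116 and 0.138), TCMR replicate 6 (-0.32 and -0.47) or TCMR replicate 10, and over all 25 omissions 4 and 11 ended them. With an estimated correlation camera gave adjusted p = 0.269 for proliferation and 0.406 for neutrophils.

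The NK cytotoxicity pathway differed by -0.13 (95% interval -0.41 to 0.10, adjusted permutation p = 0.452), with 0 of 86 members called on either basis. NK cell markers differed by 0.15 (95% interval -0.36 to 0.58, adjusted permutation p = 0.636), with 0 of 15 called and 4 risen over the list alone. The smallest p belonged to CX3CR1 (0.66), FGFBP2 (0.55), KLRF1 (0.48) and GNLY (1.32). T cell genes differed by -0.51 (95% interval -1.16 to 0.06, adjusted permutation p = 0.182), with CD8B at -0.67. The title forms differed in sign for several lists: NK cell markers lay at -0.27 in the index form and 0.49 in the letterA form, T cells at -1.24 and 0.09, interferon gamma response at -0.80 and 0.47, cytotoxic effectors at -0.64 and 0.41, and chemokines at -0.68 and 0.49. The other lists did not pass: interferon gamma response (-0.11, adjusted p = 0.828), type I interferon response (-0.22), chemokines (-0.04), cytotoxic effectors (-0.07), macrophages and monocytes (-0.49, adjusted p = 0.168), mast cells (0.16), B cells (-0.0067), plasma cells (-0.02), complement (-0.17), extracellular matrix and fibroblasts (-0.10), tubular injury (-0.37, adjusted p = 0.118), immediate early and heat shock (-0.06), proximal tubule (0.43), loop of Henle and distal tubule (0.21), collecting duct (0.14), oxidative phosphorylation (-0.04), fatty acid oxidation and peroxisome (0.09) and red blood cells (-0.02). Single TCMR biopsies moved these values. Without TCMR replicate 1 the NK cytotoxicity pathway was at -0.016, NK cell markers at 0.34, T cells at -0.26, macrophages and monocytes at -0.22 and type I interferon at -0.082. There the sign turned for chemokines, complement, cytotoxic effectors, extracellular matrix, immediate early genes, interferon gamma response, loop of Henle and red blood cells. Tubular injury was called without TCMR replicate 9 (-0.48) or caABMR replicate 11, and proximal tubule ranged from 0.19 to 0.80. The median member was opposite in sign to the score for chemokines (0.18), complement (0.019), oxidative phosphorylation (0.013) and mast cells (-0.0011), and camera went up for chemokines, complement, cytotoxic effectors, interferon gamma response, oxidative phosphorylation and red blood cells.

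None of the fixed genes passed: PRF1 (log2 change 0.36), GZMB (0.19), NKG7 (0.14), KLRD1 (0.05), FCGR3A (-0.03), CD8A (-0.64), CD3E (-0.45), MS4A1 (-0.11), COL1A1 (-1.08), HAVCR1 (-0.57) and SLC34A1 (1.52). CXCL9 was at 0.75 ± 0.72 over all forms, -1.48 in the index form and 2.12 in the letterA form, CXCL10 at 0.62, -0.95 and 1.61, and the B cell chemokine CXCL13 at -1.17 ± 0.29 (adjusted p = 0.152). Other settings called 1 gene without the filter, 1 at a mean FPKM of at least 5, 2 with upper-quartile scaling, 24 with quantile normalization, 6 without a title form term and 22 with array weights. The index form alone gave 110 and the letterA form 1.

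**Figure D4:**
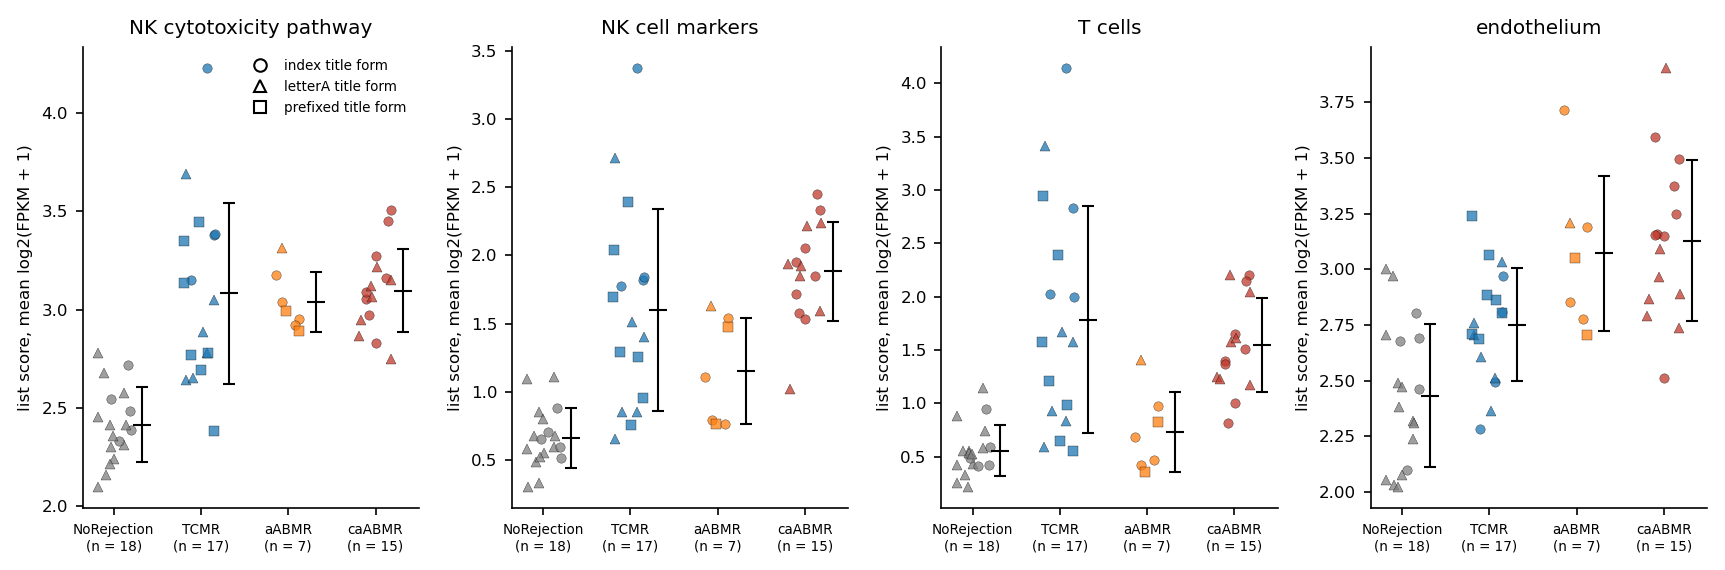
List scores (y axes, mean log2 FPKM + 1) of each biopsy for 4 lists, by group (x axes), with shape for title form and bars for mean ± SD. The mean NK cytotoxicity pathway score is 3.10 in caABMR, 3.04 in aABMR and 3.08 in TCMR, against 2.42 in NoRejection.

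The comparison of aABMR with NoRejection places the active form on the same scale. Macrophage, neutrophil and tubular injury genes were higher, and genes of the proximal tubule were lower, with camera adjusted p between 0.262 and 0.284 with an estimated correlation. The proximal tubule call, with 10 of 32 members fallen, ended in 4 of 23 omissions of 1 biopsy. The list scores rest on 5 of the 7 aABMR biopsies, 1 of them, replicate 3, of the letterA form. SERPINA3, the acute-phase protease inhibitor, averaged 96.3 ± 92.9 FPKM (SD, n = 7) against 1.92 ± 2.30 (n = 18), a log2 change of 4.15 ± 0.61 (SE, adjusted p = 3.68e-06), and S100A9 (chromosome 1, 153357854 to 153361027), which pairs with S100A8, 123.7 ± 177 against 2.22 ± 1.33 (3.59 ± 0.57, adjusted p = 9.84e-06). FCGR3A rose by 3.09 ± 0.50 (adjusted p = 1.1e-05), above the NoRejection median in 7 of 7 biopsies. SLC34A1, the phosphate transporter of the proximal tubule, averaged 32.8 ± 56.8 against 128.9 ± 70.0 (-3.02 ± 1.04, adjusted p = 0.0185).

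The NK cytotoxicity pathway was higher by 0.65 (exact permutation, adjusted p = 0.00186; camera adjusted p = 0.406 with an estimated correlation), with 47 of 86 members risen and 2 fallen (50 and 2 over the list alone). Among them were the signaling chain FCER1G (2.34) and ICAM1 (2.07). NK cell markers were higher by 0.56 (exact permutation, adjusted p = 0.00545), with 3 of 15 risen on either basis. These were FCGR3A, at 3.09 as given above, the chemokine CCL4 (1.17) and CX3CR1 (0.70). FCGR3B, close in sequence to FCGR3A, rose by 2.00. Which cells these transcripts came from was not tested. Medians, members of no other list, or leaving out replicate 3 (0.38) ended the call of the NK cell marker score. With an estimated correlation the camera adjusted p = 0.998, and relative to the shift of all genes the median member lay at -0.05. GNLY (0.44 ± 0.51), PRF1 (0.33), GZMB (0.51), NKG7 (0.72) and KLRD1 (0.0095) did not pass, nor did CD3E (0.11), CD8A (0.41) or MS4A1 (0.02). The B cell score of 1 of the 7 biopsies, at 1.68, stood apart from the next highest, at 0.596. Cytotoxic effectors were higher by 0.69 (exact permutation, adjusted p = 0.0105, 2 of 12 rose; camera adjusted p = 0.843 with an estimated correlation), a call that medians ended. Without replicate 3 the cytotoxic effector difference was 0.35 and the call ended. The 2 members that rose were SRGN (2.21) and TNFSF10 (1.35). CST7 (0.84) did not pass, nor did the members GNLY, PRF1, GZMB and NKG7 given above. T cells (0.30, adjusted p = 0.0624, 1 of 23 rose), B cells (0.05), plasma cells (0.74, adjusted p = 0.224, 2 of 14 rose) and mast cells (-0.10) did not pass the exact test. Macrophages and monocytes were higher by 1.95 with all 21 members risen, among them the lipid receptor TREM2 (1.55), and neutrophils by 1.73 (3 of 4, 4 over the list alone), with CSF3R at 2.16; both had an adjusted exact p of 0.00186 and a camera adjusted p = 0.269 with an estimated correlation.

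The interferon gamma response was higher by 1.38 (26 of 31 rose), the type I response by 0.76 (16 of 20), chemokines by 1.09 (12 of 21) and complement by 1.19 (13 of 20), with adjusted exact p from 0.00186 to 0.00669. Camera's adjusted p for them with an estimated correlation lay between 0.284 and 0.502. The type I call ended without replicate 3 (0.61). CXCL10 rose by 2.44 ± 0.69, and CXCL9 was at 1.65 ± 0.87 (adjusted p = 0.125). Tubular injury was higher by 1.81 (23 of 28 rose, 25 over the list alone, adjusted exact p = 0.00186; camera adjusted p = 0.262 with an estimated correlation), with the integrin chain ITGB6 at 2.98 and HAVCR1 at 1.83 ± 0.35. Extracellular matrix and fibroblasts were higher by 1.30 (15 of 29 rose), with TIMP1 at 2.86, COL4A1 of basement membranes at 2.01 and COL1A1 at 0.88 ± 0.55 (adjusted p = 0.198). Endothelium was higher by 0.66 (11 of 30 rose), with PECAM1 at 1.20 ± 0.27, immediate early and heat shock genes by 1.22 (12 of 16 rose), with JUNB at 2.04, and proliferation by 0.82 (16 of 17 rose). These 4 scores had adjusted exact p of 0.00186 or 0.00303. For them, camera with an estimated correlation gave adjusted p between 0.269 and 0.628. Without replicate 3 the proliferation difference was 0.47. Proximal tubule was lower, at -1.61 (10 of 32 fell, 6 over the list alone, adjusted exact p = 0.0366; camera adjusted p = 0.284 with an estimated correlation), with the gluconeogenic enzymes PCK1 (-2.24) and FBP1 (-2.12). That call ended without aABMR replicate 2 (-1.49) or 4 (-1.40) and without NoRejection replicate 10 or 11. Fatty acid oxidation and peroxisome was at -0.67 (11 of 22 fell, adjusted exact p = 0.00186) and oxidative phosphorylation at -0.41 (19 of 27 fell, adjusted exact p = 0.0147), with NDUFV1 at -0.56. The last call ended when permutation ignored title form and without replicate 3 (-0.33). Camera's adjusted p with an estimated correlation was 0.182 for fatty acid oxidation and 0.262 for oxidative phosphorylation. The mitochondrial share of FPKM was lower in these biopsies too. Collecting duct (-0.46, adjusted p = 0.0561, 4 of 16 fell), loop of Henle and distal tubule (-0.76, adjusted p = 0.111, 3 of 15 fell), podocytes (-0.02, 2 of 14 rose) and red blood cells (-0.22, 2 of 5 fell) did not pass the exact test. Without replicate 3 T cells were at 0.068, collecting duct at -0.066, plasma cells at 0.39 and mast cells at -0.048, all nearer 0 than with the 5 biopsies. T cells were called without aABMR 1 or 5 or NoRejection 1 or 15, collecting duct without aABMR 5 or NoRejection 13 or 15 and loop of Henle without aABMR 2. Plasma cells were at 0.43 without replicate 2, mast cells ranged from -0.19 to 0.0095 over the 23 omissions, and the sign turned in at least 1 omission for B cells, podocytes and red blood cells.

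Also among the largest rises were S100A8 (3.34), the protease inhibitor SLPI (3.01) and MIR1244-2, MIR1244-3 and MIR1244-4 (3.63, 3.62 and 3.62), which have equal group means (65.9 ± 147 FPKM against 0.269 ± 1.14) and are no separate evidence. Without aABMR replicate 6 these 3 calls ended (2.61, 2.60 and 2.60; adjusted p = 0.0541, 0.0565 and 0.0565). The other large falls were the fatty acid binding protein FABP1 (-3.43), the glutathione transferases GSTA1 (-3.31) and GSTA2 (-3.12), which are close in sequence, the organic anion transporter SLC22A8 (-3.01), G6PC (-2.98), BCYRN1 (-3.14) and AC008670.1, which was listed at 0 in all 7 aABMR biopsies and at 196.7 ± 783 FPKM in NoRejection. Of 30 called genes followed here, without CCL4 and CX3CR1, 23 stayed called without each aABMR biopsy in turn. Besides the 3 above, the calls of FABP1 and SLC34A1 ended without replicate 4, of PCK1 without 3 and of SLC22A8 without 2, 3, 4 or 6. By limma, 6933 genes were called, 5602 higher and 1331 lower. At least 2-fold changes were found in 914, 590 higher and 324 lower, and in 1753 (1262 and 491) at a pseudocount of 0.1. The balance turned to 377 higher and 478 lower with upper-quartile scaling and to 355 and 420 with quantile normalization. The median of all genes was higher by 0.20, and relative to it the median member of tubular injury lay at 1.11 and of the NK cytotoxicity pathway at 0.29. Higher calls were 80.8% of all calls, 56.3% with upper-quartile scaling, 54.3% with quantile normalization and 73.1% without mitochondrial transcripts. Camera called 17 of 25 lists with its preset correlation and 0 with an estimated one (adjusted p = 0.182 at the lowest), with direction down for NK cell markers, T cells, B cells and plasma cells. The index form alone gave 3439 calls.

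The comparison of TCMR with NoRejection gives the T cell-mediated form on the same scale. T cell, macrophage and interferon gamma response genes were higher, and loop of Henle and distal tubule genes were lower (camera adjusted p between 0.182 and 0.269 with an estimated correlation). CD8A, the alpha chain of the CD8 coreceptor (chromosome 2, 86784610 to 86808396), averaged 6.41 ± 10.2 FPKM (SD, n = 17) against 0.455 ± 0.320 (n = 18), a log2 change of 1.93 ± 0.31 (SE, adjusted p = 1.32e-05). LYZ for lysozyme (chromosome 12, 69348341 to 69354234) averaged 89.4 ± 115 against 6.02 ± 3.56 (2.70 ± 0.50, adjusted p = 5.79e-05). KLK1, the kidney kallikrein, had a mean of 3.06 ± 4.08 FPKM in TCMR (log2 change -2.44 ± 0.55, adjusted p = 0.0005), below the NoRejection median in 17 of 17 biopsies.

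T cell genes were higher by 1.38 (95% interval 0.85 to 2.00, adjusted permutation p = 0.000298). With an estimated correlation the camera adjusted p = 0.269. All 23 members rose, among them CD3D (2.07), CD2 (1.99) and CD3E (1.97 ± 0.36). The score difference was 2.18 in the index form and 0.95 in the letterA form. It was uneven over the biopsies, with TCMR replicates 1 and 6 at 4.14 and 3.41. TCMR replicates 2, 4, 7, 11, 13 and 15 scored from 0.554 to 0.985, below NoRejection replicate 1 at 1.139. The NK cytotoxicity pathway was higher by 0.73 (95% interval 0.51 to 0.99, adjusted permutation p = 0.000114; camera adjusted p = 0.269 with an estimated correlation), with 66 of 86 risen (68 over the list alone), including the adapter LCP2 (1.91). NK cell markers were higher by 0.98 (adjusted permutation p = 0.000398, 12 of 15 rose; camera adjusted p = 0.378 with an estimated correlation), with FCGR3A at 2.38 ± 0.40 and the receptor chain IL2RB at 1.42. Cytotoxic effectors were higher by 1.33 with all 12 risen (adjusted permutation p = 0.000489; camera adjusted p = 0.317 with an estimated correlation); NKG7 was at 1.77 ± 0.37, GZMB at 1.15, PRF1 at 1.11, KLRD1 at 0.90 and GNLY at 1.01 ± 0.41 (adjusted p = 0.0415). That last call ended at a pseudocount of 0.1, without the filter, with upper-quartile scaling and in the letterA form alone, among others. NK cell markers minus T cells, also tested after the data were seen here, lay lower in TCMR, at -0.40 (permutation p = 4e-05, below the NoRejection median in 14 of 17 biopsies). That test used 28 biopsies, and over all 35 the difference was -0.29 (permutation p = 0.0055). Tested after the data were seen, the same balance was higher in aABMR by 0.26 (exact permutation p = 0.0068) and in caABMR by 0.21 (permutation p = 0.0165), and neither of these held at a pseudocount of 0.1 (permutation p = 0.272 and 0.539). Between caABMR and aABMR it differed by 0.0098 (exact permutation p = 0.945). FCGR3A, at 3.09 in aABMR and 2.38 in TCMR against NoRejection, is among the 15 NK cell markers of this balance. Its cell source was not tested.

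The interferon gamma response was higher by 1.53 with all 31 members risen, CXCL9 at 2.34 ± 0.70 (4.71 in the index form and 1.10 in the letterA form) and CXCL10 at 1.98. Higher scores were also found for macrophages and monocytes (1.56, 20 of 21 rose), neutrophils (1.27, 4 of 4), plasma cells (1.59, 13 of 14), mast cells (0.79, 4 of 6) and B cells (0.53, 5 of 7, with MS4A1 at 0.96). Complement was higher by 1.07 (14 of 20 rose), including C1QB, chemokines by 1.11 (15 of 21), the type I interferon response by 0.87 (17 of 20) and proliferation by 0.55 (16 of 17). Tubular injury was higher by 1.01 (21 of 28 rose), with HAVCR1 at 1.18 ± 0.28, immediate early and heat shock genes by 0.56 (10 of 16), and extracellular matrix and fibroblasts by 0.68 (18 of 29), with VCAN for versican at 1.94 and COL1A1 at 1.36 ± 0.44. Adjusted permutation p for these lists lay between 0.000114 and 0.0174. Camera's adjusted p for them with an estimated correlation lay between 0.269 and 0.628. Loop of Henle and distal tubule was lower, at -0.74 (6 of 15 fell, adjusted permutation p = 0.0219), with the thiazide-sensitive transporter SLC12A3 at -2.06. Fatty acid oxidation and peroxisome was at -0.31 (9 of 22 fell, adjusted permutation p = 0.0276) and oxidative phosphorylation at -0.30 (24 of 27 fell, adjusted permutation p = 0.0111), beside the lower mitochondrial share of FPKM given above. For these 3 lists, camera with an estimated correlation gave adjusted p between 0.182 and 0.194. The fatty acid oxidation call ended without TCMR replicate 1, 2, 5 or 6 and that of loop of Henle without TCMR replicate 7 (-0.64). Endothelium (0.21, adjusted p = 0.136, 4 of 30 rose and 1 fell), podocytes (-0.36, adjusted p = 0.141, 2 of 14 rose and 3 fell), proximal tubule (-0.83, adjusted p = 0.118, 4 of 32 fell; SLC34A1 at -1.75 ± 0.83), collecting duct (-0.28, adjusted p = 0.0617, 2 of 16 fell) and red blood cells (-0.33, 1 of 5 fell) did not pass; PECAM1 was among the endothelial genes that rose (0.93 ± 0.22). Without NoRejection replicate 12 proximal tubule was at -1.05 with a call (adjusted permutation p = 0.00683), without TCMR replicate 5 it was at -0.53, and 6 of 28 omissions gave a call to collecting duct.

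Immunoglobulin constant regions made up most of the largest rises, with IGHG3 at 3.18, IGKC at 3.10, IGLC3 at 3.01, IGLC2 at 2.86, IGHG1 at 2.83, IGHG2 at 2.78 and IGHA1 at 2.65. The other large falls were GSTA2 (-2.46), GSTA1 (-2.43), albumin (ALB, -2.23), HPD of tyrosine catabolism (-2.17), AC008670.1 (-2.15, at 0.935 ± 3.86 FPKM in TCMR) and FAM151A (-2.03). By limma, 7557 genes were called, 6563 higher and 994 lower. At least 2-fold changes were found in 674, 566 higher and 108 lower, and in 1479 (1315 and 164) at a pseudocount of 0.1. The median of all genes was higher by 0.19, and relative to it the median member of the T cell list lay at 1.27 and of the NK cytotoxicity pathway at 0.36. Higher calls were 86.8% of all calls, 56.9% with upper-quartile scaling, 48.4% with quantile normalization and 75.8% without mitochondrial transcripts. Camera called 23 of 25 lists with its preset correlation and 0 with an estimated correlation (adjusted p = 0.182 at the lowest), with direction down for endothelium. The index form alone gave 1986 calls and the letterA form 2829.

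**Figure D5:**
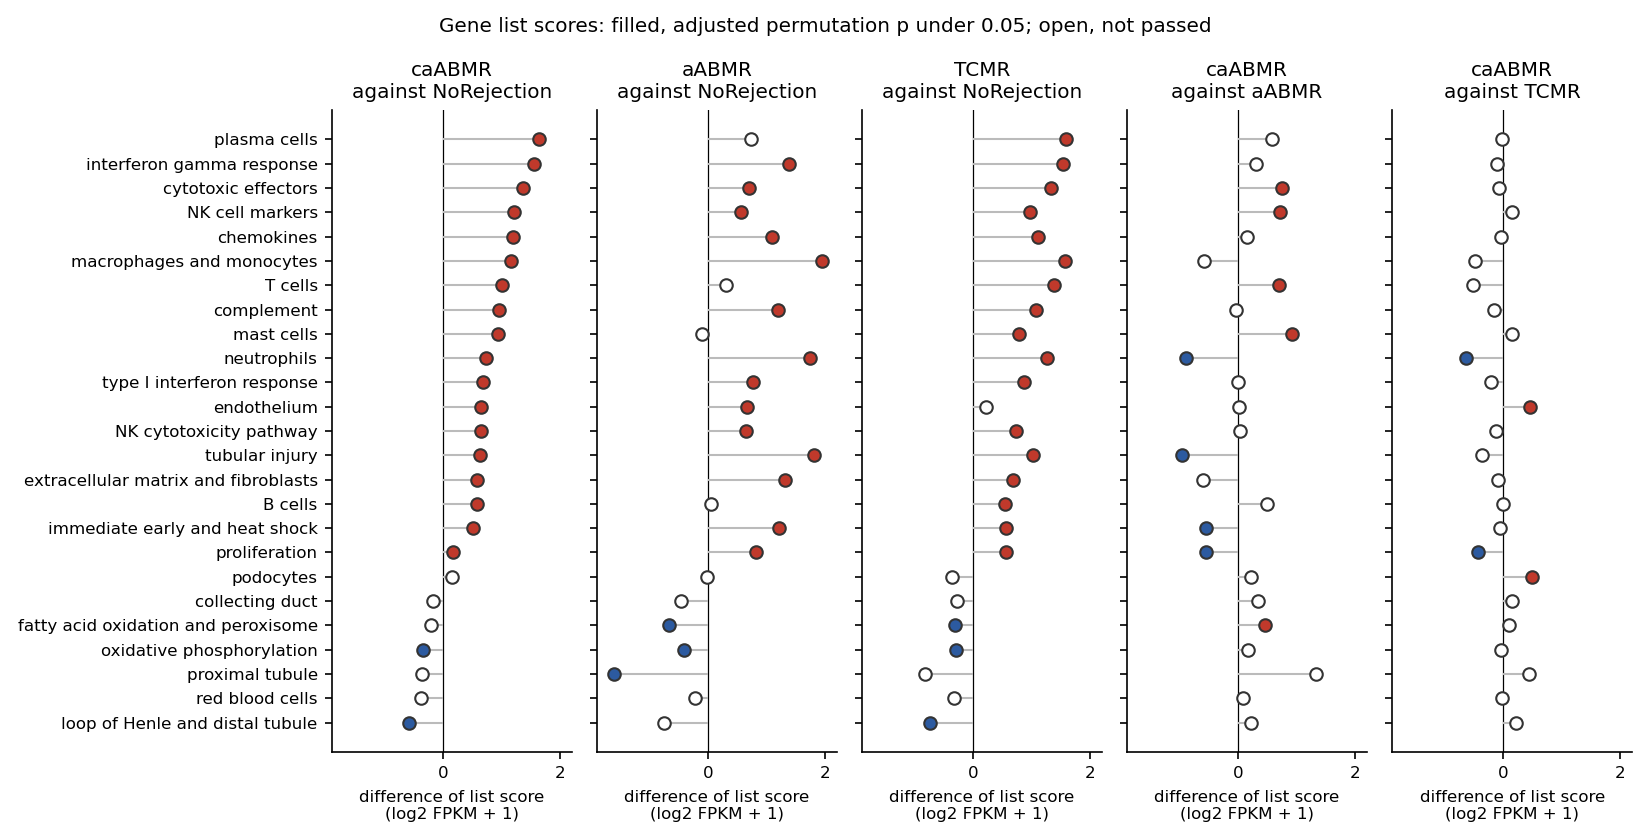
Difference of list score (x axes, log2 FPKM + 1) for the 25 lists (y axis) in the 5 comparisons; filled points have an adjusted permutation p under 0.05. Against NoRejection 20 lists pass in caABMR, 17 in aABMR and 20 in TCMR, while 9 pass between caABMR and aABMR and 4 between caABMR and TCMR.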

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

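The tests of leukocyte dilution, title form and mitochondrial transcripts below, and the counts over other splits, were chosen after the results were seen; those of podocyte content, of single aABMR biopsies and of the 100 most abundant genes were written before their results. In the 7 aABMR biopsies, the B cell list score of replicate 5 stood at 1.68 with the next highest at 0.596, a gap of 0.827 of the range. MS4A1, a member of that list, stood at 1.61 in the same biopsy with the next highest biopsy at 0.683, a gap of 0.61 of the range. These 2 were the only ones of 91 measures over the critical value of Dixon's ratio, which chance passes in about 1 group of 20. At that rate 2 passes among 91 measures are no more than chance would give.

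The 5168 calls of caABMR against NoRejection were matched by 1 of 100 splits of the same biopsies, the real one, with a highest other count of 0. Likewise only the real split reached the count for TCMR against NoRejection (7557 calls, 1 of 100, highest other 0) and aABMR against NoRejection (6933 calls, 1 of 100, highest other 135). The splits were drawn without regard to title form. A split that mixes 2 groups that differ also widens the spread within groups, which can lower its count. They are therefore a limited check and do not exclude chance by themselves. For caABMR against aABMR the 295 calls were reached by 1 of 100 splits, the real one, but another split gave 291, so chance is not excluded there. The real count fell to 28 without aABMR replicate 1 and to 3 with the 2 compared groups alone. Between caABMR and TCMR the real count was 0, which each of the 100 splits reaches by definition (100 of 100, highest other 3), so the splits decide nothing there.

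The endothelium list was higher in caABMR than in TCMR by 0.46 (permutation p = 0.00143, adjusted 0.00365; camera adjusted p = 0.0815 with an estimated correlation, which is no call). More glomeruli in the caABMR cores may contribute, as the podocyte list was also higher there, by 0.50. With the podocyte score as covariate the endothelium difference was 0.449, but the slope within groups was 0.027, so the correction removes next to nothing and does not test this. Dilution of kidney cells by infiltrating leukocytes in TCMR may contribute: measured against collecting duct genes the difference was 0.318 (95% interval -0.025 to 0.67, permutation p = 0.148), so neither can be told apart from a change in endothelium. A difference in microvessels between the 2 kinds of rejection stays open as a hypothesis.

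Tubular injury was lower in caABMR than in aABMR by a score of -0.96 (exact permutation p = 0.0066, adjusted 0.0144; camera adjusted p = 0.235 with an estimated correlation, which is no call). Leaving out in turn each of the 5 aABMR biopsies that enter this score gave differences below 0, the nearest to 0 at -0.745 without replicate 3 (exact permutation p = 0.0667) and the farthest at -1.30 without replicate 2. Replicate 3 is the only aABMR biopsy of the letterA form, so that fit is the index form alone, again at -0.745, and biopsy and title form cannot be told apart with 12 biopsies left. The call was lost there with fewer biopsies, and what in the diagnoses would cause the difference was not tested.

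Most calls against NoRejection were higher calls, 90.7% in caABMR. FPKM of a biopsy are shares, so a larger mitochondrial share in NoRejection could lower all other genes there. With mitochondrial transcripts left out the lowest share of higher calls over the 3 comparisons was 73.1%, and without the 100 most abundant genes 68.4%, both in aABMR. This argues against either as the whole cause, while the fall from 80.8% in aABMR leaves a part to them. Without the 100 genes the share fell to 75.9% in caABMR and from 86.8% to 69.6% in TCMR. The rescaled values are still shares, so a wider shift in composition is not excluded. Upper-quartile scaling and quantile normalization centre the values and cannot decide this. A rise of many leukocyte transcripts from a low level in rejection stays open and was not tested.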

How the results depend on the processing

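The alternatives without each biopsy and without the 4 biopsies of low correlation for the list scores, without mitochondrial transcripts, without the 100 most abundant genes, without the prefixed form and without those 4 biopsies for the genes were chosen after seeing the data; the rest were fixed before. Depth is unknown for FPKM, so what it limits cannot be measured here. No paired analysis was possible because the labels give nothing that pairs biopsies and replicate numbers only follow the order of the samples. Alternatives were followed for part of the genes that the naming rule takes. Over the genes followed, 2806 values kept direction and side of the threshold, 286 kept direction and lost the call, 51 gained one and 49 reversed, 0 of these from a followed gene that had passed. Over the lists the numbers were 4225, 145, 84 and 165. Of the 165, 4 came from 2 lists that had passed, in camera alone, whose direction is relative to other genes. The cause was not tested for any change below, save that a single form or 2 groups alone leave fewer biopsies and a mean FPKM of at least 5 fewer genes (7808).

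Calls of caABMR against NoRejection were 2380 at a mean FPKM of at least 5, 1570 in the index form and 1916 in the letterA form. Those of aABMR against NoRejection were 3510 at that mean and 3439 in the index form, and 5062 to 7504 without each aABMR biopsy. Those of TCMR against NoRejection were 3424, 1986 in the index form and 2829 in the letterA form. Calls of caABMR against aABMR were 151 at that mean, 592 with quantile normalization, 172 without a form term, 3 with 2 groups, 1786 with array weights, 6 in the index form and 1313 without the 4 biopsies, and 28 to 767 without each aABMR biopsy (28 without replicate 1, 578 without 2, 69 without 3, 133 without 4, 90 without 6, 767 without 7). Calls of caABMR against TCMR were 1 without the filter, 1 at that mean, 2 with upper-quartile scaling, 24 with quantile normalization, 6 without a form term, 22 with array weights, 110 in the index form, 1 in the letterA form, 1 without the prefixed form and 9 without the 4 biopsies.

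The permutation tests of biopsy scores gave 70 list calls. Camera asks another question, whether a list moved more than other genes, so its counts are not like these. With an estimated correlation it called 0 lists. For the NK cytotoxicity pathway it gave adjusted p = 0.269, 0.406 and 0.269 in caABMR, aABMR and TCMR against NoRejection. The other 9 list alternatives called 67 to 89, and leaving out each biopsy 63 to 73. Camera's direction, which is relative to other genes, was opposite to the score in the following cases. Adjusted p is given at the preset and the estimated correlation. In caABMR against NoRejection they were podocytes (0.576, 0.878) and proliferation (0.886, 0.993). In caABMR against aABMR they were chemokines (0.987, 0.998) and type I interferon (0.442, 0.899). In caABMR against TCMR they were chemokines (0.296, 0.791), complement (0.804, 0.949), cytotoxic effectors (0.608, 0.905), interferon gamma (0.436, 0.907), oxidative phosphorylation (0.198, 0.843) and red blood cells (0.212, 0.554). In aABMR against NoRejection they were B cells (0.205, 0.628), NK cell markers (0.987, 0.998), T cells (0.436, 0.905) and plasma cells (0.918, 0.993), and in TCMR against NoRejection endothelium (0.399, 0.847).

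Score differences that reversed were all of lists that had not passed. In caABMR against NoRejection, podocytes were at -0.0052 by medians. In caABMR against aABMR, z-scores gave NK cytotoxicity pathway -0.074, chemokines -0.0089, endothelium -0.035 and type I interferon -0.012. Members of no other list gave NK cytotoxicity pathway -0.014, complement 0.031 and red blood cells -0.23. Medians gave complement 0.16, red blood cells -0.33 and type I interferon -0.15, upper-quartile scaling complement 0.0080, and omitting mitochondrial transcripts type I interferon -0.012. Permutation over all biopsies gave loop of Henle -0.046, red blood cells -0.11, type I interferon -0.031 and NK cell markers minus T cells -0.082, the last also -0.062 at a pseudocount of 0.1. In caABMR against TCMR, upper-quartile scaling gave B cells 0.018, chemokines 0.0093, oxidative phosphorylation 0.0030, plasma cells 0.025 and red blood cells 0.013. Omitting mitochondrial transcripts gave B cells 0.026, chemokines 0.0049 and plasma cells 0.023. Permutation over all biopsies gave NK cytotoxicity pathway 0.014, chemokines 0.17, collecting duct -0.030, complement 0.036, cytotoxic effectors 0.21 and immediate early genes 0.064. It also gave interferon gamma 0.25, oxidative phosphorylation 0.11, plasma cells 0.015, red blood cells 0.10 and type I interferon 0.038. Medians gave chemokines 0.65 and extracellular matrix 0.042, a pseudocount of 0.1 cytotoxic effectors 0.046 and red blood cells 0.018, and z-scores red blood cells 0.056. Without the 4 biopsies of low correlation the scores were chemokines 0.21, complement 0.040, cytotoxic effectors 0.29, immediate early genes 0.047, interferon gamma 0.21 and red blood cells 0.17. In aABMR against NoRejection, upper-quartile scaling gave B cells -0.043, z-scores podocytes 0.24 and medians red blood cells 0.14.

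Among the genes followed, those that reversed had not passed either. SLC4A1, which the naming rule also takes but which was not followed, had passed in aABMR against NoRejection (log2 change -1.52, limma adjusted p = 0.0156). It was at 0.18 in the index form. In caABMR against NoRejection, COL1A1 was at -0.17 with array weights and -0.20 in the letterA form, and SLC34A1 at 0.042 in the index form. In caABMR against aABMR, FCGR3A was at 0.27 in the index form, PECAM1 at 0.014 with upper-quartile scaling and 0.0024 with array weights. In caABMR against TCMR, the index form gave GZMB -0.85, NKG7 -0.65, KLRD1 -0.59, CXCL9 -1.48, CXCL10 -0.95 and PECAM1 -0.013, and the letterA form CD3E 0.30, MS4A1 0.059 and FCGR3A 0.027. KLRD1 was at -0.071 with 2 groups and -0.033 without the prefixed form. FCGR3A was at 0.0088 at a pseudocount of 0.1, 0.019 with upper-quartile scaling, 0.011 with quantile normalization, 0.22 without a form term, 0.18 with array weights, 0.015 without the 100 most abundant genes and 0.43 without the 4 biopsies. In aABMR against NoRejection, GZMB was at -0.027 in the index form. KLRD1 was at -0.0060 with upper-quartile scaling, -0.046 with quantile normalization, -0.076 with array weights, -0.0088 in the index form and -0.16 without the prefixed form. CD3E was at -0.038 at a pseudocount of 0.1, -0.070 with quantile normalization, -0.089 with array weights and -0.30 in the index form. MS4A1 was at -0.026 with upper-quartile scaling, -0.068 with quantile normalization, -0.0085 with array weights and -0.030 without the 4 biopsies. Without each aABMR biopsy in turn, CXCL10 ranged from -0.27 to 0.59 and PECAM1 from -0.13 to 0.19 in caABMR against aABMR, and in the scores NK cytotoxicity pathway from -0.0046 to 0.145, complement from -0.26 to 0.24, endothelium from -0.080 to 0.14, red blood cells from -0.24 to 0.31, type I interferon from -0.15 to 0.16 and NK cell markers minus T cells from -0.026 to 0.045, the scores here and below without each biopsy of any group. In aABMR against NoRejection B cells ranged from -0.17 to 0.18, mast cells from -0.19 to 0.0095, podocytes from -0.19 to 0.20 and red blood cells from -0.40 to 0.054, and CD3E from -0.21 to 0.26, KLRD1 from -0.097 to 0.12 and MS4A1 from -0.17 to 0.092. In caABMR against NoRejection proximal tubule ranged from -0.58 to 0.040. In caABMR against TCMR B cells ranged from -0.089 to 0.12, chemokines from -0.16 to 0.15, complement from -0.25 to 0.011, cytotoxic effectors from -0.21 to 0.18 and extracellular matrix from -0.24 to 0.048. There immediate early genes ranged from -0.15 to 0.040, interferon gamma from -0.22 to 0.14, loop of Henle from -0.017 to 0.35, plasma cells from -0.20 to 0.21 and red blood cells from -0.18 to 0.11.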

Other observations

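Sums over gene families and the spread of scores were tested after the data were seen, on the same biopsies. T cell receptor alpha and beta variable segments, summed over 121 symbols, had a log2 sum of 4.70 ± 0.78 (SD, n = 15) in caABMR, 2.67 ± 1.09 (n = 7) in aABMR, 4.80 ± 1.70 (n = 17) in TCMR and 2.68 ± 0.73 (n = 18) in NoRejection. They were higher in caABMR than in NoRejection by 2.00 (permutation p = 1e-05, the smallest possible, adjusted p = 0.00015 over 30 tests) and than in aABMR by 1.72 (exact permutation, adjusted p = 0.0124; 2.09 in the index form and 0.60 in the letterA form), while aABMR and NoRejection differed by 0.20 (exact permutation, adjusted p = 0.768), a value of either sign when 1 aABMR biopsy was left out (-0.39 without replicate 3, 0.44 without 1). Between caABMR and TCMR the difference was -0.54 (adjusted permutation p = 0.574), with -1.86 in the index form and 0.54 in the letterA form. Immunoglobulin variable segments (272 symbols) were higher in caABMR by 3.11 and in TCMR by 2.92 against NoRejection (adjusted permutation p = 0.00305 and 0.00168), with 1.70 and 4.07 in the index and letterA forms for caABMR and 2.84 and 2.96 for TCMR; aABMR differed from NoRejection by 1.62 (exact permutation, adjusted p = 0.285) and by 0.86 without replicate 3.

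HLA class II genes (15 symbols), which present antigen to CD4 T cells, were higher against NoRejection by 1.68 in caABMR (adjusted permutation p = 0.00015), 1.55 in TCMR (adjusted permutation p = 0.00142; 2.76 in the index form and 0.89 in the letterA form) and 1.09 in aABMR (exact permutation, adjusted p = 0.0124). The last value was 0.59 (exact permutation p = 0.127) without replicate 3, the only aABMR biopsy of the letterA form. Mitochondria-encoded transcripts (37 symbols) were lower, at -0.51 in caABMR, -0.76 in aABMR and -0.62 in TCMR (adjusted permutation p = 0.00424, 0.0124 and 0.00424). Metallothioneins and cytosolic ribosomal proteins did not pass in any of the 5 comparisons. TCMR biopsies were more spread than caABMR biopsies around their group and title form mean in 19 of 25 list scores, and 5 of these passed: proliferation (mean absolute deviation 0.534 against 0.107, adjusted permutation p = 0.0005), complement (0.566 against 0.132, adjusted p = 0.001), macrophages and monocytes (0.766 against 0.267), neutrophils (0.683 against 0.253) and type I interferon response (0.526 against 0.2175). T cell genes did not pass (adjusted permutation p = 0.0912). The 7 TCMR biopsies of the prefixed form did not enter these deviations. In proliferation TCMR replicates 1, 6 and 10 scored highest, at 3.28, 2.75 and 2.56, against a TCMR mean of 1.71. No spread without these biopsies is given here. The group and title form differ in size, and causes of the spread were not tested.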
